A study of Mus musculus with 4 samples.

How the data were processed

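RNA from primary mouse embryonic fibroblasts was measured on 4 Affymetrix expression arrays, 1 for each of wild type and tri-CH1 at 21% and at 0.1% oxygen for 6 h, with 5% carbon dioxide at 37 °C. Per the labels, the authors computed 1 signal intensity per probe set with the Affymetrix statistical algorithm, which corrects background, and multiplied each array by 1 scale factor to a target signal of 500; the deposited intensity values are on a linear scale. The 2% trimmed mean was 500.2 on each array, as the scaling implies. The name and version of the software were not given in the sources used here. The scale factors were 3.46 for wild type in normoxia, 6.73 for wild type in hypoxia, 10.3 for tri-CH1 in normoxia and 8.70 for tri-CH1 in hypoxia, so the background after scaling was 139, 246, 343 and 393 in that order. The wild-type normoxia array came from another array lot than the other 3. With 1 array per group it cannot be left out, but the tri-CH1 hypoxia comparison and the genotype comparison in hypoxia do not use it. The 3' to 5' ratio of the Gapdh control probe sets was between 0.63 and 0.75 on the 4 arrays, and that of the Actb controls between 1.23 and 1.43.

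Probe sets were named through the platform annotation: 20380 of 22690 had 1 gene symbol, 691 had several, 1555 had none and 64 were controls. Of the named probe sets, 20351 matched the gene reference by gene number, which updated 0 symbols. Only probe sets with 1 symbol were used, and each gene took the probe set with the highest mean signal over the 4 arrays, which gave 12393 genes. Signals under 200 were raised to 200. A gene counted in a comparison if the brighter of its 2 arrays had a signal of at least 500, and was called higher or lower at 2-fold or more. These limits, the groups and the comparisons were fixed before the data were examined. The comparisons were hypoxia against normoxia in each genotype, which share no array, tri-CH1 against wild type at each oxygen level, which share no array either, and the difference between the hypoxia changes of the genotypes. No test of single genes was run, since 1 array per group gives no estimate of variation between cultures; a difference may come from the culture, the embryo or the array. The difference in log2 change between the 2 probe sets of a gene, over 1505 genes, divided by the square root of 2, gave an SD of 0.25 and 0.29 for the hypoxia changes and of 0.33 and 0.31 for the genotype changes; this covers error between probe sets only. The response of the genotypes was compared over genes with a mean log2 change of at least 1 in size over both, because a choice made on 1 genotype inflates that genotype's change.

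There were 22 gene lists fixed in advance. Each list's median log2 change over members at 500 or more in any array was placed among 10000 random lists of the same size, drawn in 20 bins of mean signal, as a percentile; this describes the arrays and is not a p-value. An added pair of lists, ribosome biogenesis genes and SRF and YAP targets, was written after the 2-fold calls were seen and is reported at the end. Genes were named by a rule set in advance: the 10 largest rises and falls of each hypoxia comparison, the 10 highest and 10 lowest genes by genotype among those called the same way at both oxygen levels, ranked by the smaller change, and the 10 most negative and 10 most positive differences in response among genes with a mean log2 change of at least 1 in size. Members of the lists, the targeted genes and the sex-linked genes were named as well. The alternatives were floors of 100 and 400, no floor, minimum signals of 250 and 1000, quantile normalization, cyclic loess and scaling to the same median. Others were the mean over all probe sets of a gene and only probe sets whose name ends in plain _at, without any suffix before it. The mean was taken on the log2 scale first, and means under 200 were then raised to 200. Genes chosen on 1 genotype alone and list members with no minimum signal were tried too. The probe set of each gene was kept under the other normalizations. The mean over those probe sets of a gene that reached 500 on at least 1 array was added after seeing the data. A floor of 100 or no floor cannot move a count, since a signal of 500 over one of 200 is already past 2-fold.

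The rule was tested on simulated data with a noise SD of 0.21 per array: 8 of 50 genes with a 1.5-fold change were called, 26 of 50 at 2-fold, 49 of 50 at 3-fold and 49 of 50 at 4-fold, and 3 of 3716 unchanged genes. Of 40 simulated lists of 18 unchanged genes, 1 fell outside the central 95% of random lists, against 35 of 40 with a log2 shift of 0.3. The simulated noise is that between probe sets, so variation between cultures is not in these rates. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, figures matplotlib 3.10.9, and normalization limma 3.58.1 in R 4.3.3. Probe sets for Ep300 were not analysed here.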

Results

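Gene expression was measured on 4 Affymetrix mouse arrays in primary fibroblasts grown from mid-gestation embryos. The cells were wild type or tri-CH1, a genotype that lacks the CH1 domain in both alleles of p300 and in 1 allele of CBP. The CH1 domain is a protein-binding module of these related coactivators, and HIF-1α, the oxygen-regulated transcription factor, is 1 of its known partners. Each genotype was kept for 6 h at 21% oxygen (normoxia) or 0.1% oxygen (hypoxia), giving 4 groups with 1 array each. The design asks how much of the hypoxic response remained when most CH1 domains were missing, and what else differed between the genotypes. Of 22690 probe sets, between 6066 and 6328 per array had a signal of 500 or more, and 4645 of 12393 named genes reached that level in at least 1 array. There were no replicate arrays, so no value below has a replicate error and none was tested; the number of arrays limits the precision. Rose, fell, higher and lower refer to a difference of at least 2-fold by size, after signals under 200 were raised to 200; a fold from a dimmer side under 200 is given as at least that fold. The probe sets of a gene give the only internal spread, an SD of 0.25 on the log2 scale for the hypoxia change in wild type and 0.29 in tri-CH1.

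Hypoxia in wild-type fibroblasts raised 126 genes and lowered 49 of the 4125 genes bright enough to count. With the floor of 200, Bnip3, a mitochondrial mitophagy receptor, rose most, 26.2-fold, or 4.71 on the log2 scale. Without the floor, Slc2a3, Krt19, Adm and Pgf rose more, by 4.99, 4.75, 4.74 and 6.02 on that scale. The glucose transporter Slc2a3 rose at least 21.7-fold, the keratin Krt19 at least 19.4-fold, the HIF prolyl hydroxylase Egln3 at least 18.1-fold and Ndrg1 16.5-fold. The mitochondrial adenylate kinase Ak4 rose by at least 3.80 on the log2 scale, the endoplasmic reticulum oxidase Ero1a 11.6-fold, the vasodilator peptide Adm at least 10.9-fold, the cyclin Ccng2 9.46-fold and the lipoprotein receptor Vldlr 8.86-fold. Dimmer probe sets of Vldlr showed log2 changes of at least 1.97 and at least 0.62, and another stayed under 200. Those of Slc2a3 gave at least 3.10, 1.58 and 1.22, and that of Egln3 at least 2.35. Those of Ak4 gave at least 3.32 and 1.74, with a further one of Ak4 under 200. The normoxia signals of these dimmer probe sets were under 200, so the bounds do not show a smaller rise. The falls were smaller. The chemokine Ccl7 fell at least 5.57-fold, the flap endonuclease Fen1 4.41-fold, Wdr77 3.53-fold, Sephs2 3.24-fold and Rrs1 3.20-fold. Rcl1 fell at least 3.04-fold, the noncoding RNA Neat1 at least 2.64-fold, the ribosomal protein gene Rps27 2.63-fold, Hyal2 2.59-fold and the PDGF receptor Pdgfrb 2.58-fold. Other probe sets of Fen1 and Pdgfrb gave log2 changes of -0.55 and -0.94, and those of Sephs2 -1.11 and -0.59. Those of Wdr77 were under 200 in hypoxia, so their changes lay at least as far below 0 as -1.51 and -0.56. Rcl1, Neat1 and Hyal2 were under 2-fold with a floor of 400. Scaling each array to the same median put the median of all genes at -0.13 on the log2 scale, against -0.053 as deposited, and gave 116 higher and 72 lower, so that the share of higher genes went from 72.0% to 61.7%.

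Hypoxia in tri-CH1 fibroblasts raised 139 genes and lowered 43 of 4358. With the floor, Bnip3 again led, at 21.1-fold, followed by Ero1a at 12.3-fold, Ndrg1 at 10.3-fold and Egln3 with at least 9.91-fold. Egln1, another HIF prolyl hydroxylase, rose 8.99-fold. Egln3 went from 139.5 to 1981, so its place depends on the floor. So does that of Ndrg2, which rose by 3.81 on the log2 scale without it, against 3.62 for Ero1a. The pyruvate dehydrogenase kinase Pdk1 rose 8.57-fold, Ak4 8.45-fold, the lactate transporter Slc16a3 8.40-fold, the phosphofructokinase Pfkl 8.24-fold and Slc2a3 7.65-fold. The dimmer probe sets of Slc2a3, under 200 in normoxia, showed log2 changes of at least 2.23, 1.04 and 0.59. Fen1 fell 6.65-fold, the tetraspanin Cd151 5.30-fold, Smoc1 at least 3.20-fold, Ccl7 at least 2.65-fold and the RNase component Pop5 2.61-fold. Cenpq fell 2.59-fold, the keratin Krt8 at least 2.51-fold, the m6A reader Ythdf1 2.49-fold, the folate enzyme Mthfd1 2.48-fold and the chaperone Hsph1 2.45-fold. The other probe sets of Cd151 ranged from a log2 change of -0.69 to 0.37, another of Fen1 gave -0.50, those of Ythdf1 gave -0.57 and -0.03, and another of Mthfd1 went the other way, at 1.59. Median scaling gave 152 higher and 26 lower genes, and cyclic loess 28 lower. The further probe sets of Pop5 and Krt8 stayed under 200, and Smoc1, Ccl7, Cenpq, Pop5, Krt8 and Mthfd1 were under 2-fold with a floor of 400.

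The hypoxic response of the genotypes overlapped in its rises and in its falls. Among the risen genes, 79 rose in both genotypes, which is 62.7% of the wild-type rises (Wilson 95% interval, 54.0 to 70.6, for counting alone) and 56.8% of the tri-CH1 rises, against 3.33 if the choices were independent. By size, 9 genes fell in both, 18.4% of the wild-type falls and 20.9% of the tri-CH1 falls, against 0.30, and 42 of the 49 wild-type falls and 36 of the 43 tri-CH1 falls had the same sign in the other genotype. The independent counts of 3.33 and 0.30 use only calls bright enough to count in both genotypes, while the percents use all calls. Such calls were 111 of the 126 wild-type rises and 115 of the 139 tri-CH1 rises. For the falls they were 43 of 49 and 27 of 43. No gene rose in one genotype and fell in the other. Across the 4645 genes, Pearson's r of the hypoxia changes was 0.61 and Spearman's rho 0.44; without the known HIF targets, r was 0.51. Genes are not independent replicates, so these describe the arrays only.

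**Figure D1:**
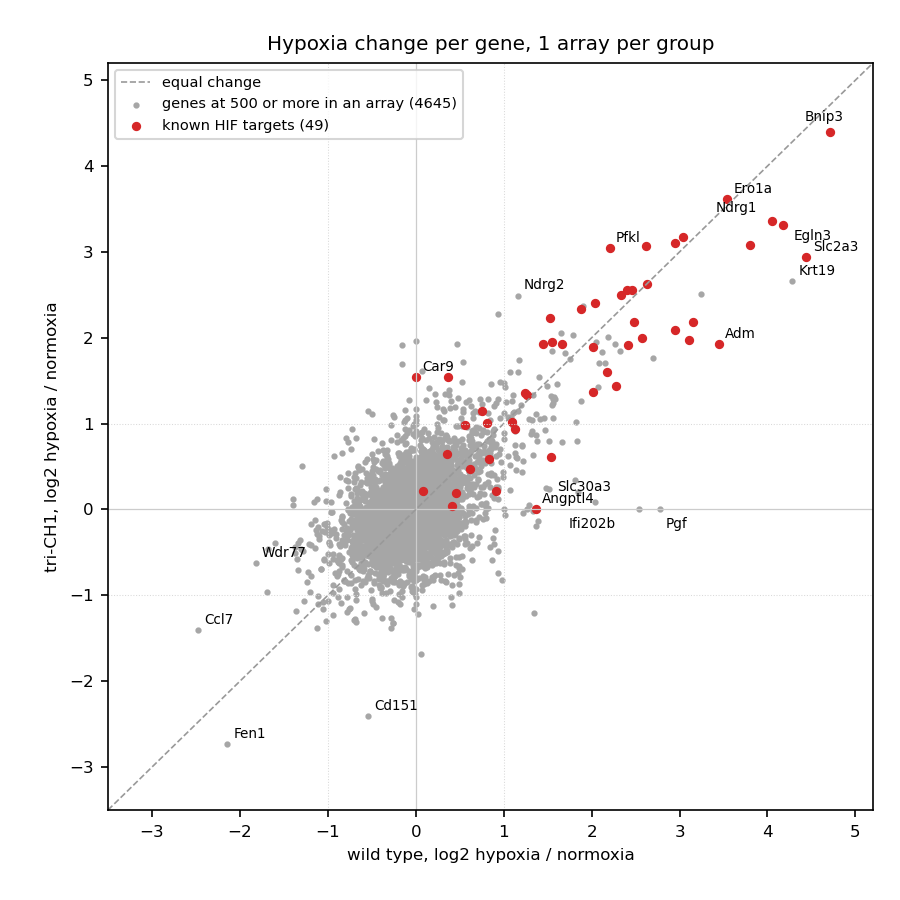
Each point is a gene, with its log2 change from normoxia to hypoxia in wild type on the x axis and in tri-CH1 on the y axis; red points are the 49 measured known HIF targets and the dashed line marks equal change. Bnip3 lies at 4.71 and 4.40, while Pgf and Ifi202b lie at 2.77 and 2.54 in wild type and at 0 in tri-CH1, where their signals were under 200 on both arrays.

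The known HIF targets, a list of 63 genes that share HIF as an activator, rose in both genotypes. Of its 49 measured members, 37 rose in wild type and 38 in tri-CH1, 34 of them in both, and none fell in either. The median log2 change was 2.02 in wild type and 1.92 in tri-CH1, each above all 10000 random lists matched on signal. Among the 18 measured genes of glycolysis and glucose uptake, a part of that list, 13 rose in wild type and 14 in tri-CH1, with medians of 1.93 and 1.99. The glucose transporter Slc2a1 rose 6.19-fold in wild type and 6.19-fold in tri-CH1, the hexokinase Hk2 2.89-fold and 4.70-fold, and the triosephosphate isomerase Tpi1 3.16-fold and 3.79-fold. Of the 31 other known HIF targets, 24 rose in each genotype. The growth factor Vegfa rose 4.04-fold in wild type and 2.58-fold in tri-CH1, while a dimmer probe set gave the opposite order, with log2 changes of 1.61 and 2.35. The collagen hydroxylase P4ha2 rose 4.11-fold and 5.31-fold, and the mitochondrial protein Higd1a 5.03-fold and 5.63-fold. Pgk1 and Pkm, glycolytic enzymes that were among the brighter genes on every array, stayed under 2-fold in both genotypes, at log2 changes of 0.36 and 0.84 in wild type and 0.65 and 0.59 in tri-CH1.

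The HIF-target response had a similar median in the genotypes. The tri-CH1 change minus the wild-type change of each gene had a median of -0.073 and a mean of -0.15 over the 49 targets; 26 were smaller in tri-CH1 and 23 larger, but 16 were smaller by over 0.5 and 4 larger by as much. With median scaling these counts were 13 and 9, with the mean over probe sets 9 and 5 of 47, and with the mean over only those probe sets that reached 500 on an array 11 and 5. That last setting was chosen after seeing the data. Counts with median scaling carry its shift of the difference of all genes, which is given below. Among genes induced on average, 14 of 36 targets (38.9%) had a difference of -0.5 or lower and 2 (5.56%) of 0.5 or higher, against 20.3% and 12.7% of the 79 other genes, which were less strongly induced. The order turned with the mean over probe sets, where 7 of 35 targets were at -0.5 or lower against 24.2% of the other genes. That mean takes in probe sets under 200 on every array, and a mean that fell under 200 was raised to 200 afterwards. Ak4 has such a probe set, and its changes in wild type and tri-CH1 went from 3.80 and 3.08 to 1.49 and 1.95. With probe sets at 500, 8 of 35 targets (22.9%) were that low against 20.8%. With median scaling 11 and 6 of 37 targets were past these limits, against 17.7% and 19.0% of the others. The median of -0.073 lay at percentile 5.72 of random lists, whose central 95% ran from -0.092 to 0.12. It became -0.15 with a floor of 100, -0.19 with no floor and -0.14 with a minimum of 1000, but 0.069 with median scaling, where the median difference of all genes was 0.18, 0.065 with the mean over probe sets and 0.059 with the mean over those at 500. This difference has no replicate check, and the random lists describe these arrays only. After the floor, the rise was smaller in tri-CH1 by 1 log2 unit or more for Slc2a3, Adm, Angptl4 and Pfkfb3. Slc2a3 and Adm were under 200 in wild-type normoxia. Taking their tri-CH1 signals as given, their differences lay at least as far below 0 as -1.51 and -1.52, and with no floor they were -2.05 and -2.82. The tri-CH1 normoxia signal of Slc2a3, 241, was itself close to the floor. A floor of 400 left -0.52 for Adm, and the mean over probe sets -0.82 for Slc2a3. Both normoxia means of Slc2a3 then lay under 200 and were raised to the floor, so -0.82 does not show a smaller difference. Pfkfb3 was under 200 in both normoxia arrays, at 131 and 88.8, and its difference went from -1.14 to -0.58 with no floor. The lipase inhibitor Angptl4 rose 2.58-fold in wild type and stood at 302 and 304 in tri-CH1; its other probe set was under 200 on every array, and the mean over both did not reach 500. Insig2, a sterol sensor, rose 2.91-fold in wild type and had a log2 change of 0.62 in tri-CH1. The carbonic anhydrase Car9 had signals of 34.0 and 197 in wild type, both under the floor, and rose 2.91-fold in tri-CH1, from 321 to 933. Car12, of the same family, went from 64.5 to 259 in wild type and from 164 to 581 in tri-CH1. Their differences of 1.54 and 1.17 came from the floor: without it the log2 rise of Car9 was 2.54 in wild type and 1.54 in tri-CH1, and the difference of Car12 was -0.18. Adm went from 81.4 to 2182 in wild type and from 865 to 3287 in tri-CH1, so that its smaller rise went with a higher normoxic level. The glycolysis genes had a median difference of 0.12 (0.25 with median scaling), with a mean of -0.02, and the other known HIF targets one of -0.27, below all 10000 random lists; those lists were matched on signal and not on the size of the rise. The value of -0.27 became -0.13 with quantile normalization and -0.12 with median scaling, or -0.30 relative to all genes there. A shift near this size was also seen in the 10 housekeeping genes, none of them past 2-fold with oxygen. Their median difference was -0.23, at percentile 1.5 of random lists, with a mean of -0.01.

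**Figure D2:**
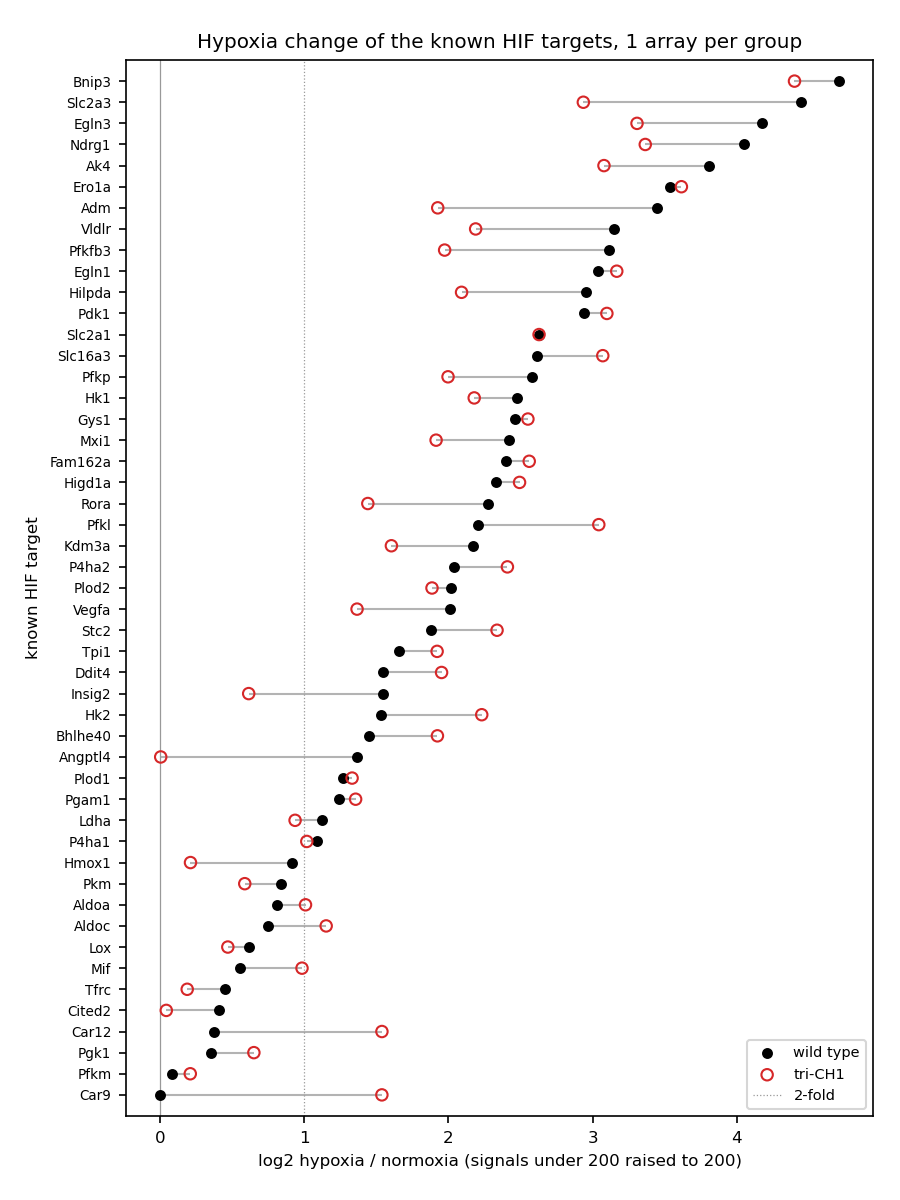
Each line is 1 of the 49 measured known HIF targets, with its log2 change from normoxia to hypoxia in wild type (filled) and tri-CH1 (open); the dotted line is 2-fold. The symbols of 34 targets are past 2-fold in both genotypes, and those of Slc2a3 and Angptl4 are 1 log2 unit or more lower in tri-CH1 at every floor tried, while the gaps of Adm, Pfkfb3, Car9 and Car12 depend on the floor.

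Beyond the known targets, genes were compared when their mean log2 change over both genotypes was at least 1 in size, a choice that favours neither genotype. These were 115 induced and 19 repressed genes. The induced genes had a median log2 change of 1.56 in wild type and 1.46 in tri-CH1, and a median difference of -0.13, as the 79 of them that are not known HIF targets also had; 66 of the 115 rose less in tri-CH1. Pgf, the placental growth factor, went from 21.1 to 1368 in wild type and from 7.20 to 39.3 in tri-CH1, under the floor on both tri-CH1 arrays. The interferon-inducible gene Ifi202b went from 324 to 1885 in wild type and stayed under 200 in tri-CH1. The log2 difference was -1.64 for Rhbdd3 and -1.47 for Zdhhc12; another probe set of Rhbdd3 had log2 changes of 1.12 in wild type and -0.13 in tri-CH1. The mean over all of its probe sets gave 0.38, since 1 of them was under 200 on every array, and the mean without that 1 gave -1.45. The zinc transporter Slc30a3 and Krt19 were under 200 in wild-type normoxia, as Slc2a3 and Adm were, so their differences lay at least as far below 0 as -1.94 and -1.62. Among the repressed genes, Cd151 had a difference of -1.86, but its probe sets disagree: another, nearly as bright, had log2 changes of -0.33 in wild type and -0.20 in tri-CH1. Slc30a3, Rhbdd3, Zdhhc12 and Adm were already higher in tri-CH1 in normoxia, by at least 2.70-fold, 3.09-fold, 2.41-fold and at least 4.32-fold. Among induced genes, the difference was positive for the adiponectin receptor Adipor2, at 1.46, for Spg21 at 0.97 and Pfkl at 0.84. Adipor2 was 2.36-fold lower in tri-CH1 in normoxia, with a log2 difference of 0.22 in hypoxia. Among repressed genes it was positive for Rrs1 at 1.22, Wdr77 at 1.20 and Sephs2 at 0.74, which here means a smaller decrease in tri-CH1. With the mean over probe sets that of Wdr77 was 0.63 and that of Sephs2 0.34. The corepressor Rcor2 was under 200 in tri-CH1 normoxia, so its difference was at least 1.34. Ndrg2, Gga1 and Ccl7 had a signal under 200 in both genotypes, so their differences of 1.33, 1.18 and 1.07 depend on the floor. Without it they were 0.64, 2.05 and 1.22. Of these, Ccl7 fell in both genotypes. The repressed genes had a median difference of 0.11. With median scaling the induced genes' median turned to 0.0088. The median difference of all genes also went from 0.028 to 0.18 there, so the induced genes stayed below all genes. With the mean over probe sets the median was -0.020 for the induced and -0.093 for the repressed genes.

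Cholesterol and fatty acid synthesis genes had median log2 changes of 0.45 in wild type and 0.67 in tri-CH1, each above all random lists; by size, 3 of 16 rose in wild type and 6 in tri-CH1. The squalene epoxidase Sqle rose 2.04-fold and 2.38-fold, the isopentenyl isomerase Idi1 2.15-fold and 2.04-fold, and Lss 2.01-fold and 2.17-fold; Fdft1, Mvd and Scd2 rose in tri-CH1, with log2 changes in wild type of 0.57, 0.33 and 0.72. Cell cycle genes had medians of -0.33 and -0.39, at percentiles 0.09 and 0.01, but none of the 18 measured members passed 2-fold in either genotype. Immediate early genes had medians of 0.10 in wild type and 0.56 in tri-CH1. Ier3, a stress-response gene, rose 3.75-fold in wild type and 5.19-fold in tri-CH1, and the phosphatase gene Dusp1 and the transcription factor gene Klf6 rose 2.38-fold and 2.18-fold in tri-CH1, with log2 changes of 0.23 and 0.65 in wild type. Among the 7 measured inflammatory NF-kB targets, the chemokines Ccl2 and Ccl7 fell in both genotypes, Ccl2 at least 2.57-fold and 2.28-fold; the adhesion molecule Vcam1 fell 2.18-fold in tri-CH1 and had a log2 change of 0.19 in wild type. The list medians were -0.11 and -0.72. The 45 oxidative phosphorylation genes had medians of -0.10 and -0.07 and none passed 2-fold with oxygen. The 16 measured genes of ER stress and the integrated stress response also held none past 2-fold, with medians of -0.01 and 0.28. Among 4 measured HIF pathway components, the ubiquitin ligase gene Vhl rose 2.78-fold in wild type and had a log2 change of 0.93 in tri-CH1, and Hif1a itself changed by 0.55 and 0.38. No difference between the genotypes in these groups has a replicate check.

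The genotype comparison asked what differed at a given oxygen level. In normoxia, 137 genes were higher in tri-CH1 and 151 lower, of 4333; in hypoxia, on a separate pair of arrays, 159 were higher and 140 lower, of 4233. The enkephalin precursor Penk was higher by at least 3.81 on the log2 scale in normoxia and at least 3.85 in hypoxia, the annexin Anxa8 by 10.9-fold and 16.5-fold, and the water channel Aqp1 by at least 14.2-fold and at least 10.7-fold. The small proteoglycan Ogn was 9.86-fold and 6.19-fold higher, the Wnt agonist Rspo2 at least 9.55-fold and at least 6.04-fold, the pentraxin Ptx3 5.93-fold and 10.3-fold, and Cbr2 at least 6.75-fold and at least 5.68-fold. Igfbp4, an IGF-binding protein, was 5.50-fold and 6.53-fold higher, the calcification inhibitor Mgp 5.03-fold and 8.23-fold, and Crabp2, a retinoic acid-binding protein, 4.98-fold and 7.43-fold. Lower in tri-CH1 were Rpl39l, by 9.88-fold and 6.92-fold, the muscle ankyrin-repeat gene Ankrd1, by 6.82-fold and 6.55-fold, and the protease inhibitor Tfpi2, by at least 6.37-fold and at least 6.30-fold. Gng11 was 5.71-fold and 5.45-fold lower, Plac8 5.32-fold and 6.35-fold, the skeletal actin Acta1 5.01-fold and 8.37-fold, the scaffold Akap12 5.01-fold and 5.19-fold, Igfbp5 5.22-fold and 4.21-fold, and the smooth muscle actin Actg2 5.66-fold and 4.11-fold. Among all genes past 2-fold, 71 were higher at both oxygen levels, 51.8% of those higher in normoxia, and 80 of the 151 lower in normoxia were lower at both, against 3.53 and 4.19 if independent. The independent counts again use only calls bright enough at both oxygen levels. In normoxia these were 108 of the 137 higher and 137 of the 151 lower genes. Pearson's r across the 4645 genes was 0.70 and Spearman's rho 0.58. Median scaling put the median of all genes at -0.20 in normoxia, against 0.030 as deposited, and gave 81 higher and 262 lower there, so that the share of higher genes went from 47.6% to 23.6%. In hypoxia it gave 135 higher and 174 lower, and the share went from 53.2% to 43.7%.

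**Figure D3:**
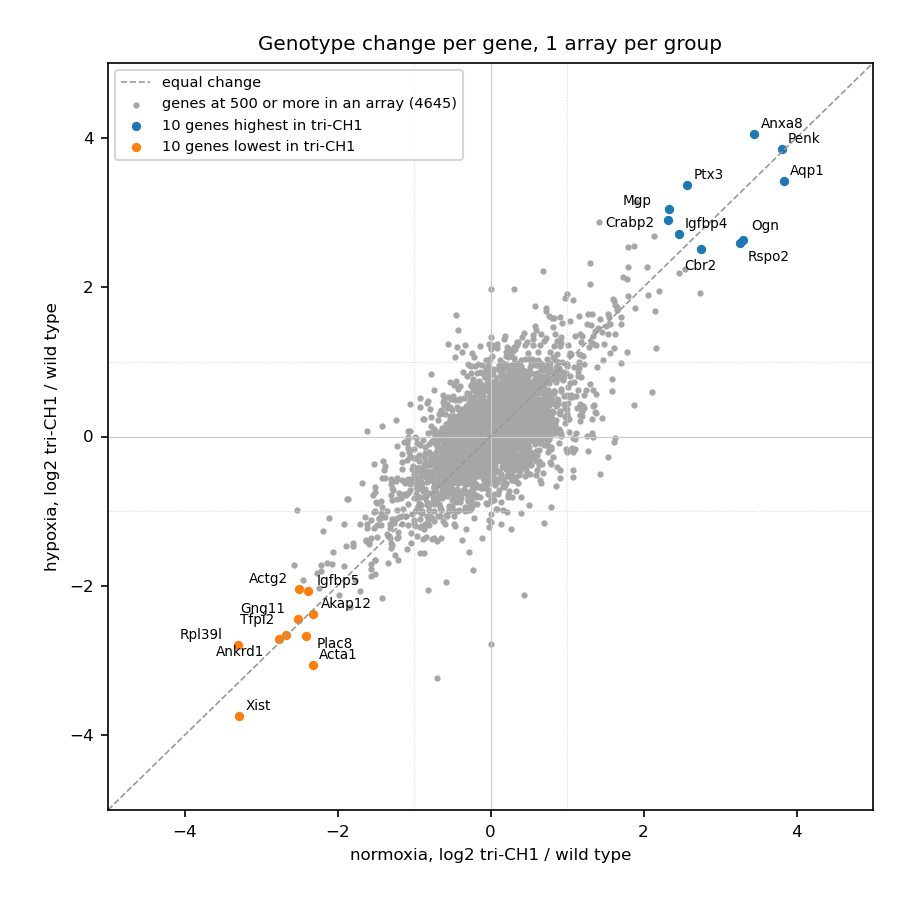
Each point is a gene, with its log2 difference of tri-CH1 from wild type in normoxia on the x axis and in hypoxia on the y axis; coloured points are the 10 highest and 10 lowest genes by the smaller of the 2 changes, and the dashed line marks equal change. Penk lies at 3.81 and 3.85, and Xist at -3.28 and -3.75.

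The embryos of the genotypes differed in sex-linked transcripts, which moved with the genotype. Xist, the noncoding RNA of the inactive X chromosome, had signals of 3096 and 3523 in the wild-type arrays and 318 and 263 in tri-CH1, in normoxia and hypoxia. The Y-linked gene Eif2s3y stood at 4.30 and 22.8 in wild type and 242 and 363 in tri-CH1, and Uty at 49.2 and 81.0 against 276 and 347. A dimmer probe set of Xist gave at most 529 in wild type and at most 9.00 in tri-CH1, and a further one stayed under 200. With the mean over all its probe sets the tri-CH1 side lay under 200 and was raised to the floor. The log2 difference in normoxia was then at least as far below 0 as -0.43, and with the mean over those at 500 as -2.48. These bounds come from the floor and do not show a smaller difference. Of the targeted genes, Crebbp, which encodes CBP, had signals between 29.6 and 87.7 on the 4 arrays, too dim to compare; Ep300, which encodes p300, was not analysed here.

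The p53 targets, of which 2 of 10 were lower in tri-CH1 in normoxia and 4 in hypoxia, had a median log2 difference of -0.53 in normoxia and -0.50 in hypoxia, each at percentile 0.08 of random lists. Pmaip1, a BH3-only gene, was lower in tri-CH1 by at least 2.85-fold and at least 3.15-fold, and the kinase gene Plk2 by 2.70-fold and 2.03-fold; Ccng1 and Mdm2 were 2.29-fold and 2.07-fold lower in hypoxia, with log2 differences of -0.99 and -0.58 in normoxia. Immediate early genes had a median of -0.31 in normoxia, where Dusp1, Ier3, Klf6, Myc and Egr2 were lower, Dusp1 by 4.33-fold and Myc by 2.11-fold; in hypoxia the median was 0.03, Dusp1 was lower and Egr1 2.44-fold higher. Cell cycle genes had medians of 0.31 and 0.28, at percentiles 99.6 and 98.8; 1 of 18 was higher in normoxia and 2 in hypoxia, and the cyclin Ccnd1 was higher by 1.32 and 1.27 on the log2 scale. Among 27 fibroblast markers and extracellular matrix genes, the proteoglycan Lum was 4.40-fold and 6.40-fold higher in tri-CH1, while the surface glycoprotein Thy1 was 3.43-fold and 3.78-fold lower and the matrix protein Tnc was lower, with log2 differences of -1.89 and -1.46. That list had a median of 0.18 and a mean of -0.03 in normoxia, and the median became -0.041 with median scaling; relative to the median of all genes it was 0.15 as deposited and 0.16 with that scaling. In hypoxia the median was 0.25. Cholesterol and fatty acid synthesis genes had a median of -0.29 in normoxia, where 1 of 16 was lower, and -0.083 in hypoxia, at percentile 14.9, where none passed 2-fold. With median scaling the normoxia medians were 0.091 for cell cycle, -0.53 for immediate early and -0.51 for cholesterol genes; relative to all genes they were 0.29, -0.33 and -0.31, against 0.28, -0.34 and -0.32 as deposited. Among the NF-kB targets, the prostaglandin synthase gene Ptgs2 was 2.37-fold and 2.15-fold lower, Ccl7 was 2.10-fold lower in normoxia and Vcam1 2.26-fold lower in hypoxia, while the chemokine Cxcl5 was at least 3.26-fold higher in normoxia. Housekeeping genes had medians of 0.04 and 0.05, with none of 10 past 2-fold.

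Markers of other cell types were mostly too dim to measure. Of 96 such genes in 8 lists, 8 reached 500 on any array, and none of the interferon response genes did. The measured markers were Acta1 for muscle, Csf1r and Lyz2 for leukocytes, Flt1 for endothelium, Krt8, Krt18 and Krt19 for epithelium and Nes for neural cells. Lyz2 had signals of 856 and 792 in wild type and 862 and 568 in tri-CH1, and Csf1r ranged from 625 to 701. None of the erythroid, cartilage and bone, or adipocyte markers reached 500.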

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

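The explanations weighed for the differences between genotypes, other than those for the HIF targets, were tested only after the result was seen, as were the comparisons of the targets with all induced genes. The flagged differences below were not tested, since each group is 1 array; a gene was flagged when it passed 2-fold on one side and moved the other way, beyond the spread between probe sets, on the other.

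Between the genotypes, the hypoxia change of Bola2 was -0.54 on the log2 scale in wild type and 1.15 in tri-CH1, a difference of 1.69. That of the exosome gene Exosc4 was -1.30 and 0.50, a difference of 1.80, and that of Pmepa1 -0.50 and 1.11, a difference of 1.61. Between the oxygen levels, the tri-CH1 difference from wild type was 0.70 in normoxia and -1.16 in hypoxia for Cd151, a difference of -1.86 from 1 of 6 disagreeing probe sets. It was -0.44 and 1.20 for Cnot3, a difference of 1.63, and -0.56 and 1.24 for Exosc4, again 1.80. The DNA repair gene Faap24 went from 1.07 to -0.45, a difference of -1.53, Myo1h from 0.40 to -1.02, a difference of -1.41, and Phldb1 from -1.06 to 0.44, a difference of 1.50. Rps27 went from -0.46 to 1.06, a difference of 1.52, and the amino acid transporter Slc7a5 from -0.33 to 1.22, a difference of 1.55. The zinc transporter Slc30a3, under 200 in wild-type normoxia, went from at least 1.44 to -0.51. Its difference lay at least as far below 0 as -1.94. Outside the named genes, 7 probe sets with several genes or none were at least 2-fold higher in hypoxia than in the normoxia control in both genotypes. Those with several genes included 3 shared by Bnip3l and its pseudogene, with log2 changes of 2.18 to 2.30 in wild type and 2.04 to 2.67 in tri-CH1.

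The hypoxia change of each known HIF target in tri-CH1 minus that in wild type had a median of -0.073. It turned to 0.069 with median scaling (-0.11 relative to all genes there) and to 0.065 with the mean over probe sets. A median over members that go both ways decides none of the explanations: it lay at percentile 5.72 of random lists, relative to the mean change it was -0.038 against -0.11 for the other induced genes, and the hypoxia arrays alone gave -0.048. The larger differences were more one-sided as reported: 14 of 36 induced targets were at -0.5 or lower, at percentile 97.8 of draws from all 115 induced genes, whose central 95% ran from 5 to 14, but with the mean over probe sets 7 of 35 were, against 24.2% of the other induced genes, and with the mean over those at 500 it was 22.9% against 20.8%. Among genes with a mean change of 2 or more, 10 of 23 targets and 3 of 7 other genes were that low, and the induced members of the other known HIF targets, at a median of -0.31, lay at percentile 7.58 of such draws. A chance list, compression on the tri-CH1 arrays with their higher scale factors, the separate lot of the wild-type normoxia array and a loss of CH1 function all stay open. So do the culture and the embryo with its sex, which cannot be told apart from the genotype.

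Many genes differed between tri-CH1 and wild type at both oxygen levels. The separate lot of the wild-type normoxia array does not account for this as a whole, because the hypoxia pair does not use that array and the changes still went together across genes, with r = 0.70. Striated muscle cells in the wild-type cultures would bring their abundant transcripts. Of the muscle list, 1 of 17 markers, or 5.88%, reached 500 in a wild-type array, Acta1 at 3494, which argues against a large share of such cells. The list was built on striated muscle and could not detect smooth muscle cells, so those were not tested and stay open. For other cell types in the tri-CH1 cultures, 0 markers of leukocytes, endothelium, epithelium, neural, erythroid, cartilage, bone or fat cells were 2-fold higher there at both oxygen levels. At most 2 markers of a type reached 500 in a tri-CH1 array, too few for that rule to decide. By the measure used for muscle, 2 of 15 leukocyte, 2 of 13 epithelial, 1 of 12 endothelial and 1 of 14 neural markers reached 500 there. Of the erythroid, cartilage and bone, and adipocyte markers, 0 of 6, 0 of 12 and 0 of 7 did. The counts were the same in the wild-type arrays, so most listed markers of these types were dim in both genotypes. That measure was set for muscle and carried over to these types, for which the rule could not decide, so no conclusion on them is drawn. A share of any of these types, and a small share of muscle cells, stays open. The sex of the embryos cannot be told apart from the genotype, as Xist differed by -3.28 in normoxia. With the means over its probe sets the tri-CH1 side was under the floor, so the values of -0.43 (all) and -2.48 (those at 500) are bounds. The embryo, the litter and the CH1 deletion stay open.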

How the results depend on the processing

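All but 1 of these alternatives were planned; the mean over probe sets at 500 or more on an array was chosen after seeing the data. Of 215 alternative values of the main results, 161 were labelled as within limits, 50 as moved and 4 as reversed. Of 1289 further values of lists and named genes, 1079, 206 and 4 were so labelled. These limits are not given here, and the tallies do not measure stability. Counts with a floor of 100 or no floor could not move, nor could means for genes with 1 probe set. A gene's log2 change could not move under another minimum signal. Some changes of sign were labelled as moved. The HIF-target difference went from -0.073 to 0.069, 0.065 and 0.059 in settings below. The targets' genotype median in hypoxia went from -0.048 to 0.026 with quantile normalization. Medians below are log2 and "difference" is the tri-CH1 hypoxia change minus that of wild type; except where stated, the cause was not tested. A floor of 100 gave a difference of -0.15 for the HIF targets and 0.32 for the repressed genes, and no floor -0.19 and 0.24, with a wild-type HIF-target change of 2.20. A floor of 400, which by construction lowers folds of dim genes, left 24 and 18 genes lower in hypoxia in wild type and tri-CH1, 85 and 101 higher in tri-CH1 in normoxia and hypoxia, HIF-target changes of 1.67 and 1.67, and 65.0% of the tri-CH1 rises shared. A minimum of 1000, which admits fewer genes, gave 19 lower in wild type, 86 higher and 9 lower in tri-CH1, 66 higher and 92 lower by genotype in normoxia and 79 and 87 in hypoxia. It also gave a wild-type HIF-target change of 2.11, differences of -0.14 for the targets and 0.44 for the repressed genes, 70.9% of the tri-CH1 rises shared, and r = 0.74. A minimum of 250 gave 70 lower in tri-CH1, a wild-type HIF-target change of 1.77 and r = 0.49; list members with no minimum also gave 1.77. Quantile normalization put the HIF targets at 0.026 in tri-CH1 against wild type in hypoxia. Cyclic loess gave 28 lower in tri-CH1 in hypoxia and a wild-type HIF-target change of 2.08. Median scaling put the median of all genes at -0.13 in wild-type hypoxia (-0.053 as deposited) and -0.20 by genotype in normoxia (0.030 as deposited), and gave 26 lower in tri-CH1 in hypoxia and 81 higher and 262 lower by genotype in normoxia. It gave HIF-target changes of 1.94 and 1.99 and genotype differences of -0.20 and -0.13. Differences in response were 0.069 for the targets, 0.0088 (reversed) for the induced and 0.30 for the repressed genes. The median difference of all genes went from 0.028 to 0.18, so the induced genes stayed below all genes despite the change of sign. Relative to the median of all genes, the targets' difference was -0.11 there and -0.10 as reported. Median scaling reversed the fibroblast list in normoxia, to -0.041. Choosing the brightest probe set again after this scaling would change 7 measured genes, among them Cd151, from -1.72 to 0.28, and Pdk1, with a difference of 0.0093 for the targets and -0.0016 for the induced genes. The mean over probe sets gave a wild-type HIF-target change of 1.81, differences of 0.065 for the targets, -0.020 for the induced and -0.093 (reversed) for the repressed genes, and r = 0.63; it reversed the hypoxia change of Mthfd1 in tri-CH1, to 0.16, and the difference of Rhbdd3, to 0.38. The mean over probe sets at 500 gave 0.059 for the targets, 0.14 (reversed) for Mthfd1 and -1.45 for Rhbdd3, so the reversal of Rhbdd3 came from a probe set under 200 on every array. Only probe sets without a suffix gave 27 lower in tri-CH1 in hypoxia, a wild-type HIF-target change of 1.95 and a difference of 0.28 for the repressed genes. Genes chosen on wild type alone had differences of -0.37 (induced) and 0.80 (repressed), and on tri-CH1 alone 0.26 and -0.59, both reversed, as a choice on 1 genotype does by construction. Of the known HIF targets, 16 had a rise smaller in tri-CH1 by over 0.5 and 4 one larger by as much; these counts were 18 and 2 with no floor, 15 and 2 with a minimum of 1000, 14 and 7 with quantile normalization, 13 and 9 with median scaling, 9 and 5 with the mean over probe sets, 11 and 5 with those at 500 and 10 and 4 without suffixed probe sets. Of the induced targets, 14 were at -0.5 or lower and 2 at 0.5 or higher, against 12 and 5 with quantile normalization, 11 and 6 with median scaling, 7 and 3 with the mean over probe sets, 8 and 3 with those at 500 and 9 and 2 without suffixed probe sets. Among 80 named values, 16 went under 2-fold in at least 1 setting. The background, 139 to 393 after scaling, had already been corrected for in the signals, so it is not itself a limit of detection. How far its noise limits dim genes was not tested.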

Other observations

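The ribosome biogenesis list and the SRF and YAP list were written after the 2-fold calls were seen, and all tests in this part use them. Their predictions were set before the medians were computed, but for members not seen before. The medians below are over all measured members, some of them among the calls already seen, so they do not test the predictions as worded.

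Genes of ribosome assembly had mostly negative hypoxia changes, though few passed 2-fold. Of 41 measured members, 35 had a negative log2 change in wild type and 36 in tri-CH1. The box C/D snoRNP gene Nop56 fell 2.12-fold in wild type, Wdr75 2.28-fold, and Nop16 2.03-fold in tri-CH1. The abundant nucleolar genes Npm1 and Ncl had log2 changes of 0.23 and 0.15 in wild type. The median was -0.39 in wild type, below all 10000 random lists, and -0.24 in tri-CH1, at percentile 0.11. The list was prompted by Rrs1 and Rcl1, which are not in it. Members past 2-fold, such as Nop56 and Wdr75, were among the calls already seen, so the list is not independent of these arrays. A hypothesis is that 6 h at 0.1% oxygen lowered transcripts of ribosome assembly in both genotypes; the medians of -0.39 and -0.24 are consistent with it, without replicates. The difference between the genotypes, 0.13, lay at percentile 92.3. It was 0.28 with median scaling, where the median difference of all genes was 0.18, 0.095 with quantile normalization and 0.092 with cyclic loess.

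Known SRF and YAP targets mostly had negative log2 differences in tri-CH1, but only 3 of 29 passed 2-fold in normoxia and 4 in hypoxia. Of the 29 measured SRF and YAP targets, 24 had a negative difference in normoxia and 23 in hypoxia. Fhl2, a cofactor that binds actin-linked proteins, was 2.14-fold and 2.85-fold lower, and Crim1 2.06-fold and 2.67-fold lower. The calponin Cnn1 was 2.28-fold lower in normoxia, and Srf itself 2.17-fold lower in hypoxia. The tropomyosin Tpm4 and the actinin Actn4 had log2 differences of 0.19 and 0.14 in normoxia. The list median was -0.45 in normoxia and -0.36 in hypoxia, each below all random lists, and with median scaling it was -0.68 and -0.45, where the medians of all genes were -0.20 and -0.035. Ankrd1, Actg2, Acta1 and Ccn2, which prompted the list, are not in it. Members past 2-fold, such as Fhl2 and Crim1, were among the calls already seen, so this list is not independent of the arrays either. A hypothesis is that transcripts of SRF and YAP targets were lower as a group in the tri-CH1 culture; the medians of -0.45 and -0.36 are consistent with it, but the activity of SRF or YAP was not measured, and embryo and sex differ along with the genotype.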
